A study of Mus musculus with 3 samples.

How the data were processed

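Per the labels' protocols, lungs of GFI1B-GFP reporter mice were perfused with PBS, digested with collagenase, DNase and Dispase and enriched on Percoll, and live CD45+ lineage-negative CD90.2+ IL-7R+ cells were sorted by flow cytometry. The antibodies of the lineage gate are not given in the sources used here. Libraries were made with the 10x Chromium Single Cell 3' v3.1 dual index kit, per the labels' protocols. Per the submitters' processing notes the authors used Cell Ranger 6.0.1 and genome build mm10. The annotation and the settings of cell calling are not given in the sources used here. Per the file headers, each deposited matrix holds counts: whole UMI counts per gene and cell barcode, with no normalisation, for 32285 genes in 1 library. The gene identifiers were the same in the 3 libraries. Raw reads were not used here, and alignment, read filtering and barcode calling were not repeated.

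The 3 libraries were taken as 3 groups from the labels: IL-18R+ pool, IL-18R- CD103- GFP- and IL-18R- ST2+. The first mixes an IL-18R+ CD103+ GFP- sort with an IL-18R+ CD103- GFP+ sort, and its barcodes are not assigned to either. Samples and comparisons were fixed before the data were examined, as were most alternatives (those chosen later are named as such). With 1 library per group no test was run, and no p value or standard error was made from cells. No paired analysis was possible because the labels give no replicate numbers shared between the libraries.

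Barcodes were kept with at least 500 genes and at most 10% mitochondrial UMIs. Scrublet, in scanpy 1.11.5 with exact neighbours, was run per library with an expected rate of 0.8% per 1000 barcodes (1.35%, 1.522% and 1.408%). Its calls were 4, 11 and 11 cells (0.241%, 0.584% and 0.678%), 26 of 5164 in total or 0.503%, which is barely above the 0.5% under which calls are not to be trusted, so doublets from it are likely incomplete. Barcodes in order pool, IL-18R- CD103- GFP- and IL-18R- ST2+ were 1688, 1903 and 1760, with 9139839, 9730760 and 8133323 UMIs. The filter removed 29, 20 and 138 (1.72%, 1.05% and 7.84%). The 5138 cells kept had median genes of 1860, 1787 and 1567, median mitochondrial UMIs of 2.88%, 3.59% and 3.83%, ribosomal protein UMIs of 22.86%, 26% and 29.22%, and 14.26%, 16.14% and 17.7% of UMIs in the top 20 genes. Globin UMIs in kept cells were 59, 10 and 12649, of which 11990 were in 1 cell of the IL-18R- ST2+ library. No ambient RNA removal was run, since empty droplets are not used here. A total of 13236 genes had no UMI in any barcode, and 1 gene of the lists is absent from the features.

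Counts were summed over the kept cells of each library and divided by the library total of UMIs, giving UMI counts on the CPM scale (UPM). Intervals are 95% Poisson or Clopper-Pearson limits and hold counting error only. A gene was measured in a pair if either library reached 20 UPM. It was called higher by the size rule at a ratio of at least 2 with the sums raised to a floor of 3 UMIs, which is 0.334, 0.313 and 0.38 UPM. Fold values in the text are as counted with their counting interval, and against 0 UMIs the ratio to the floor is given as at least that fold. The rule was tried on simulated sums with 50 shifted genes per step: all 50 were called at 2.5-fold, 4-fold and 8-fold, 0 at 1.5-fold, and 0 unshifted genes were called. Shifted genes had at least 20 UPM, and only counting error at the full library totals was simulated. At that depth a cut at 2 nearly fixes these outcomes. The trial does not cover variation between libraries or the smaller sums within classes. Named genes were chosen by rule: the sort genes, the 12 called genes with the largest ratio per direction among those of at least 50 UPM in the higher library, leaving out predicted genes, and from each list up to 4 measured members with the largest absolute log2 ratio. Within a class the 8 largest ratios per direction were taken.

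There were 19 gene lists, written from general knowledge before the data were examined: ILC2, ILC1 and NK, ILC3, ILC progenitor, T cell, gamma delta T cell, B cell, myeloid, mast cell and basophil, platelet and erythroid, stroma, endothelium and epithelium, cycling, immediate early and heat shock, interferon response, residency and trafficking, secreted cytokines and mediators, cytokine receptors, transcription factors of ILC, and GFI1B partners. Some genes are in more than 1 list. Each list is described by its counts of genes higher in either library or neither, its median log2 ratio, and the percentile of that median among 10000 random lists of genes matched within 50 ranks of level. The percentile describes these libraries and is not a test. Loci were read from GENCODE M21 on GRCm38: Gfi1b on chromosome 2 at 28609450 to 28621982 (minus strand), Il18r1 on chromosome 1 at 40465552 to 40500854, Il1rl1 on chromosome 1 at 40429570 to 40465415 and Itgae on chromosome 11 at 73090583 to 73147446 (all plus strand).

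For clusters, counts were scaled per cell and log transformed, and 2000 variable genes, 30 principal components, 15 exact neighbours and Leiden resolution 1.0 were used, giving 17 clusters over the 3 libraries together. A clustering with scanpy defaults was looked at first and replaced by exact neighbours so that reruns give the same clusters. A cluster took the name of the cell type list with the largest share of markers raised (at least 2-fold over all other cells and 20 UPM), with at least 3 markers raised and no other list having more genes among its 10 leading genes. Leading genes needed 50 UPM and a UMI in 25% of the cluster's cells, with a pseudocount of 5 UPM. An ILC name needed Cd3e below 100 UPM and a T cell name at least that. A cluster of low median depth with no list gene among its leading genes took no name. Other clusters were left unnamed, and no name was taken from a reference atlas. This naming rule was changed once after the clusters were seen. As first written it had no minimum share of cells and no use of Cd3e. Under it 1 globin-rich cell set the leading genes of cluster 2 and left its 806 cells unnamed, and cluster 6, with Cd3e at 466.6 UPM, was named ILC1 and NK-like. Cluster 6 holds 2.05%, 19.87% and 0.81% of the libraries. The replaced rule gives 47.18% ILC2-like cells in the IL-18R- ST2+ library, and 11.84%, 24.68% and 0.99% ILC1 and NK-like cells.

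Classes or single unnamed clusters with at least 50 cells in both libraries were compared within the class by the same size rule. Counting error alone was drawn from 100 simulated pairs of sums with equal levels. For shares of cells with a UMI, each cell was thinned at random to 2000 UMIs, leaving out 19, 19 and 14 cells below that depth.

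Alternatives fixed before the data were examined were: all barcodes without a filter, a stricter filter (1000 genes, 5% mitochondrial UMIs; 1604, 1718 and 1376 cells), Scrublet calls kept, TMM factors, median-of-ratios factors, totals without mitochondrial and ribosomal protein genes, each cell weighted equally, no minimum level, a pseudocount of 5 UPM, only clusters named as an ILC class, no cycling clusters, resolutions 0.5 and 2.0, 15 principal components, sort genes or cycling and immediate early genes left out of the variable genes, each library clustered on its own, and no thinning or thinning to 4000 UMIs (356, 461 and 511 cells lie below that depth). Chosen only after seeing the data were: leaving out the myeloid, B cell, erythroid and stromal clusters, leaving out cells with more than 50% globin UMIs, equal cell weights within classes, the first naming rule as an alternative, the simulated counting error, and the shift of 0.25 log2 from which a list median counts as moved.

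Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. Trajectories, RNA velocity, receptor sequences and any data from outside these libraries were not analysed here. Some single genes are not reported here.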

Results

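Lymphocytes from perfused and digested lungs of GFI1B-GFP reporter mice were profiled as single cells with 10x Chromium 3' chemistry. All sorts were gated on live CD45+ cells that were lineage negative and positive for CD90.2 and IL-7R, a gate meant to hold innate lymphoid cells (ILC). GFI1B is a zinc finger repressor of blood cell genes, and the reporter marks cells that use its gene. The 3 libraries are 3 groups with 1 library each: the IL-18R+ pool, which mixes an IL-18R+ CD103+ GFP- sort with an IL-18R+ CD103- GFP+ sort, the library labelled IL-18R- CD103- GFP-, and the IL-18R- ST2+ library. Cells of the pool are not mapped to either of its 2 sorts in the sources used here, so the GFP+ cells cannot be read apart. With 1 library per group no difference has a replicate check, and every interval below is 95% counting error only. Values are UMI counts on the CPM scale (written UPM), each library scaled to its own total.

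After filtering, the pool kept 1655 of 1688 barcodes, the library labelled IL-18R- CD103- GFP- 1872 of 1903, and the IL-18R- ST2+ library 1611 of 1760. They held 8970571, 9598728 and 7891960 UMIs, with medians of 4930, 4768 and 4568 UMIs per cell. Counts of the X-inactivation transcript Xist (2, 1 and 0 UMIs) and of Y-linked Ddx3y (1618, 1453 and 1297 UMIs) show male cells in all 3 libraries.

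IL-18R is the receptor for the alarm cytokine IL-18, CD103 is an integrin that holds lymphocytes in epithelium, and ST2 is the receptor for IL-33 that arms ILC2. Il1rl1, the ST2 gene, reached 867.8 UPM (847.4 to 888.6; 93.11% of cells) in the IL-18R- ST2+ library, against 4.905 (3.564 to 6.585) in the pool and 5.522 (4.136 to 7.222) in the library labelled IL-18R- CD103- GFP-. Itgae, the CD103 gene, stood at 99.77 UPM (93.34 to 106.5; 33.78% of cells) in the pool, 3.438 (2.367 to 4.828) in the library labelled IL-18R- CD103- GFP- and 2.788 (1.747 to 4.221) in the IL-18R- ST2+ library. Il18r1 went against 1 label: 663.3 UPM (646.5 to 680.4; 86.65% of cells) in the pool, 591.8 (576.6 to 607.4; 86.22%) in the library labelled IL-18R- CD103- GFP- and 15.71 (13.07 to 18.73; 5.9%) in the IL-18R- ST2+ library. For that reason the second library is named by its label throughout, and directions drawn against it are directions against the label, not against cells without Il18r1 transcript. The ratio of Il18r1 in the pool to that library was 1.12 (1.08 to 1.16), or 1.02 under TMM scaling. Gfi1b had 0 UMIs in every barcode of all 3 libraries, and no feature of the files is named GFP, so neither the reporter nor its host gene can be read from these counts. The shared gates were present as transcript in all 3: Ptprc (CD45) 616.9, 790 and 658.1 UPM, Il7r 1828, 1639 and 1090, and Thy1 (CD90) 376.8, 458.3 and 174.2, in the order above.

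**Figure D1:**
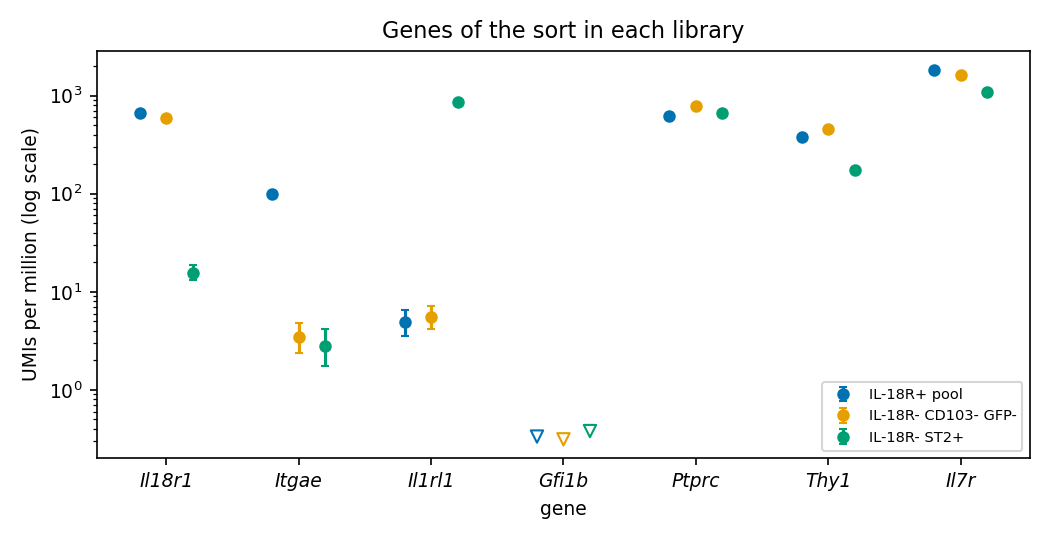
Levels of the sort genes (UPM, log axis) in each library, with 95% counting intervals; open triangles mark the limit of 3 UMIs for Gfi1b. Il18r1 stands at similar heights in the pool (663.3) and the library labelled IL-18R- CD103- GFP- (591.8), while Itgae (99.77 against 3.438) and Il1rl1 (867.8 in the IL-18R- ST2+ library) follow the labels.

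The 17 clusters were named from fixed marker lists, and the sort gates themselves set the shares that follow. Cells named gamma delta T cell-like, with Trdc (delta chain constant region), Tcrg-V6 and the IL-17 gene Il17a among the leading genes, made up 46.65% (44.22 to 49.08) of the pool, 59.51% (57.24 to 61.74) of the library labelled IL-18R- CD103- GFP- and 0.06% of the IL-18R- ST2+ library. ILC2-like cells made up 96.65% (95.65 to 97.47) of the IL-18R- ST2+ library, which was gated on ST2, and 0.12% and 0.8% of the other 2. Each library clustered on its own gave gamma delta shares of 39.46% and 14.8%, which turns their order, and an ILC2-like share of 24.02%. In that setting the clusters differ, and a marker must exceed cells of the same library. Which of these moved the shares was not tested. ILC1 and NK-like cells, led by the natural killer receptor gene Ncr1 and the chemokine gene Xcl1, were 9.79% (8.4 to 11.32) of the pool and 4.81% (3.88 to 5.88) of the library labelled IL-18R- CD103- GFP-. That order did not hold: resolution 2.0 gave 2.66% and 3.47%, and the naming rule first written, which counted cluster 6 in this class, gave 11.84% and 24.68%. At resolution 2.0 most pool cells of this class (cluster 7), 116 of 162, separated as ILC progenitor-like, with 24 of 90 from the library labelled IL-18R- CD103- GFP-. The ILC progenitor-like cluster, led by Tox2, Cacna1e, Sox4 and Batf3, held 7.01% of the pool, 1.34% of the library labelled IL-18R- CD103- GFP- and 0.12% of the IL-18R- ST2+ library. In pool cells of cluster 7, without thinning, Tcf7 had a UMI in 68.52%, Gata3 in 64.2% and Zbtb16 in 45.06%. Tbx21 had one in 16.67% and Ifng in 5.56%, so the ILC1 and NK name covers a mixture. At the main resolution no cluster took that name.

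ILC3-like cells, led by Il22, were 2.51% (1.85 to 3.32; 47 cells) of the library labelled IL-18R- CD103- GFP-, 0.12% of the pool and 0 of the IL-18R- ST2+ library, and with resolution 0.5 or 15 principal components no cluster took that name. A T cell-like cluster led by the regulatory T cell genes Foxp3 and Ctla4 held 1.03%, 1.18% and 0.12%. Cycling-like cells held 1.93%, 0.53% and 0.37%. Cells other than T cells and ILC were most frequent in the pool: stroma, endothelium and epithelium-like 3.75%, 0.85% and 0.81%, myeloid-like 2.9%, 0.53% and 0.37%, and B cell-like 1.27%, 0.16% and 0.31%. No cluster was named platelet and erythroid-like. Of the cells, 32.45%, 29.11% and 1.12% stayed unnamed, almost all in 3 clusters. Cluster 5, led by Cd40lg, Trac and Ccr6 with Cd3e at 628 UPM, held 23.69% of the pool and 8.23% of the library labelled IL-18R- CD103- GFP-. Cluster 6, led by Ccl5, Ly6c2 and Klrd1 with Cd3e at 466.6 UPM, held 2.05% and 19.87%, so it is mostly 1 library. Cluster 9, led by Ccr10, Itgae and Cd7 with Cd3e at 22.2 UPM, held 6.71% and 1.01%. Leading genes of a cluster only describe how it was formed.

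**Figure D2:**
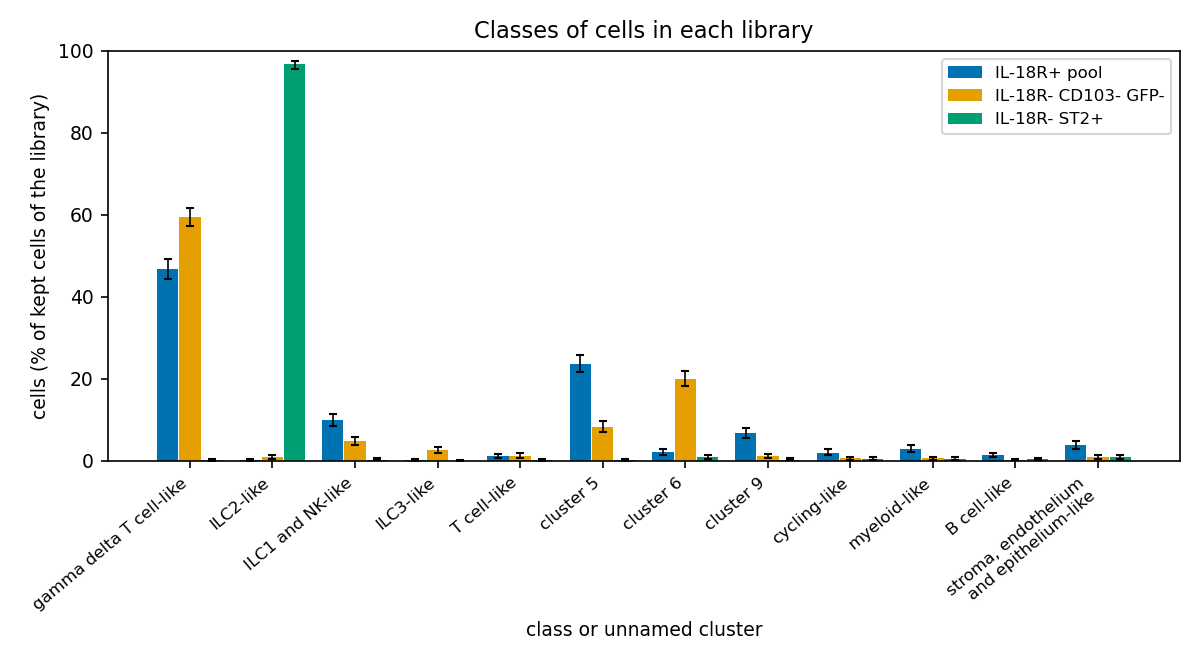
Percent of kept cells per named class in each library, with 95% counting intervals. Gamma delta T cell-like cells lead the pool (46.65%) and the library labelled IL-18R- CD103- GFP- (59.51%), and ILC2-like cells fill the IL-18R- ST2+ library (96.65%).

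The pool and the library labelled IL-18R- CD103- GFP- were close to each other. The largest ratios on the pool side include Itgae, Ccr10, a receptor for epithelial chemokines, and genes of cells outside the lymphocytes. Those on the other side include the chemokine gene Ccl5, the NK receptor genes Klrd1 and Klrc1, and Ccr7, which guides cells to lymph nodes, while the granzyme gene Gzma lies on the pool side. Of 5812 measured genes, 148 were higher in the pool and 46 in the library labelled IL-18R- CD103- GFP- by the size rule (76.3% in the pool). Without myeloid, B cell, erythroid and stromal clusters, an alternative added after the clusters were seen, the split was 59 to 51 (53.6%). Under TMM it was 119 to 57 (67.6%). TMM moved log2 ratios of the 3 pairs by -0.14, -0.28 and -0.15, and median-of-ratios scaling by -0.15, -0.32 and -0.17.

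Residency and trafficking genes split by direction: of 13 measured, 2 were higher in the pool, 2 in the library labelled IL-18R- CD103- GFP- and 9 neither (median log2 -0.16, percentile 0.08 among 10000 matched random lists). Itgae, set by the CD103 gate, was 29-fold higher in the pool (20.5 to 42.4), and Ccr4, a receptor for skin and lung homing, 2.01-fold (1.58 to 2.59; 21.4 against 10.63 UPM), a call that ended under TMM (1 against 2 higher). Ccr10, which guides cells to epithelium, was 23.9-fold higher in the pool (15.9 to 37.7; 59.86 against 2.5 UPM). Ccr7 was 3.04-fold higher (2.63 to 3.51) in the library labelled IL-18R- CD103- GFP-. Of 12 ILC1 and NK genes, 5 were higher in the library labelled IL-18R- CD103- GFP-, 1 in the pool and 6 neither (median log2 -0.84, percentile 0). The 5 were Ccl5 (2284 against 242.8 UPM; 9.41-fold, 9 to 9.83), Klrd1 (4.53-fold, 4.01 to 5.12), Xcl1 (2.6-fold, 2.23 to 3.03), Ifng (interferon gamma; 2.77-fold, 2.19 to 3.54) and Tbx21 (the T-bet gene; 2.14-fold, 1.69 to 2.73). The pool gene was Gzma, a granzyme, at 43.36 against 1.979 UPM, with 52.2% of its UMIs in 3 cells. With clusters named as an ILC class only, which drops cluster 6 and every cluster with high Cd3e, Ccl5, Ly6c2, Gramd3, Klrd1, Lef1 and the ILC1 and NK median turned to the pool side. Ly6c2 (a memory T cell marker; 293.3 against 31.88 UPM), Ms4a4b (466.3 against 119.6) and Klrc1 (69.28 against 12.26) were also higher in the library labelled IL-18R- CD103- GFP-.

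Of 17 ILC progenitor genes 3 were higher in the pool, 1 in the library labelled IL-18R- CD103- GFP- and 13 neither (median log2 0.16, percentile 79.34). The 3 were Tox2, a relative of the ILC regulator TOX (6.05-fold, 4.14 to 9.11), Sox4 (4.49-fold, 3.57 to 5.69) and the stem cell factor receptor gene Kit (2.89-fold, 2.45 to 3.41), and the 1 was Lef1 (2.42-fold, 2.14 to 2.74). Under TMM Tox2 fell below the minimum level, leaving 2 and 1. Of 8 ILC2 genes 1 was higher in the pool, 0 in the other library and 7 neither (median log2 0.54, percentile 100), the 1 being Il17rb, the IL-25 receptor gene (31.99 against 8.334 UPM; 3.84-fold, 2.99 to 4.98). This median does not follow the ILC2-like cells, which were 0.12% of the pool and 0.8% of the other library. Without thinning, Il17rb had a UMI in 35.19% of ILC1 and NK-like and 0.65% of gamma delta T cell-like cells of the pool. Of 13 ILC3 genes 1, Ccr6 (53.4 against 12.81 UPM; 4.17-fold, 3.41 to 5.12), was higher in the pool and 12 neither (median log2 0.25, percentile 98.83). With clusters named as an ILC class only, Ccr6 and the ILC3 list turned to the library labelled IL-18R- CD103- GFP-. That setting holds 162 ILC1 and NK-like, 2 ILC2-like and 2 ILC3-like cells of the pool, against 90, 15 and 47. The turn therefore cannot be told apart from this difference in composition. Il17a (499.9 against 364.8 UPM) and Il22 (43.59 against 69.28) were neither. Of 20 transcription factors of ILC, 2 (Tbx21 and Lef1) were higher in the library labelled IL-18R- CD103- GFP- and 18 neither (median log2 0.12, percentile 58.74), among the latter Gata3, the ILC2 regulator (141.8 against 91.26 UPM). None of 8 partner genes of GFI1B was called (median log2 0.08, percentile 42.52), among them Hmg20b (46.49 against 37.71 UPM) and Hdac2. The ILC progenitor, transcription factor and GFI1B partner medians changed sign under TMM (-0.02, -0.01 and -0.06).

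Of 11 T cell genes 1, Cd8b1 (24.69 against 9.698 UPM), was higher in the library labelled IL-18R- CD103- GFP- and 10 neither (median log2 -0.26, percentile 0.01), or 2 and 9 under TMM, which adds Cd6. All 9 gamma delta T cell genes were neither (median log2 -0.22, percentile 0.21), with Trdc at 1160 and 1709 UPM and Trdv4 at 548.2 and 710.9. Of 13 cytokine receptor genes 1 (Il17rb) was higher in the pool and 12 neither (median log2 -0.03, percentile 6.37), or 1 and 1 under TMM. Of 8 secreted mediators 2 (Ifng and Xcl1) were higher in the library labelled IL-18R- CD103- GFP- and 6 neither (median log2 -0.53, percentile 0). Of 15 immediate early and heat shock genes, which respond to tissue handling, 1 was higher in the pool (Atf3, 2.08-fold, 1.96 to 2.21) and 14 neither (median log2 0.23, percentile 99.5), and under TMM the call of Atf3 ended. With clusters named as an ILC class only, the median of this list turned to -0.64. All 5 interferon response genes were neither (median log2 0.19, percentile 82.36).

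Markers of cells outside the T cells and ILC moved with the pool genes. Of 6 stroma, endothelium and epithelium genes 5 were higher in the pool and 1 neither (median log2 4.18, percentile 100), among them the fibroblast gene Dcn (30.1 UPM against 0, at least 96.3-fold) and the endothelial gene Cdh5 (4.41-fold). Of 5 myeloid genes 4 were higher in the pool (median log2 1.4, percentile 100), including Lyz2 (513.1 against 97.72 UPM) and Cd14 (5.13-fold). Of 5 B cell genes 3 were higher in the pool (median log2 2.9, percentile 99.98), including Ebf1 and Cd79a (25.64 against 3.438 UPM). Apart from these, of 9 cycling genes, which mark proliferation in any cell type, 6 were higher in the pool and 3 neither (median log2 1.79, percentile 100), with Mki67 at 35.78 against 8.751 UPM. The B cell and stromal medians turned below 0 without the myeloid, B cell, erythroid and stromal clusters, and Ebf1 and Cd14 turned with them. Single cells carried some of the largest ratios: Sftpc, a surfactant gene of alveolar epithelium, had 99.9% of its pool UMIs in 3 cells, and Sftpa1 (72.91 UPM against 0) all of them in 1 cell. No mast cell and basophil gene and no platelet and erythroid gene reached the minimum level in this pair.

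Against the IL-18R- ST2+ library the pool had higher levels of most ILC1 and NK, T cell and gamma delta T cell genes and of 7 of 13 ILC3 genes, and lower levels of most ILC2 genes. IL-17 and IL-22 protect barrier surfaces from bacteria and fungi, while IL-5, IL-13 and amphiregulin drive eosinophil recruitment, mucus and tissue repair. Of 5930 measured genes, 732 were higher in the pool and 257 in the IL-18R- ST2+ library (74% in the pool), a split that moved to 476 and 388 (55.1%) under TMM and 450 and 412 (52.2%) under median of ratios.

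ILC2 genes were on the ST2 side: of 16 measured, 14, among them the gated Il1rl1, were higher there, 0 in the pool and 2 neither (median log2 -3.18, percentile 0). Gata3 stood at 849 against 141.8 UPM (5.99-fold, 5.64 to 6.36), Il5 at 168.5 against 1.226 (137-fold, 76.6 to 276), Klrg1, an inhibitory receptor of mature ILC2, at 162.3 against 3.456 (47-fold, 32.9 to 69.4) and Csf2 at 692.4 against 13.49 (51.3-fold, 42.9 to 62). Of 13 secreted mediators 9 were higher in the IL-18R- ST2+ library, 3 in the pool and 1 neither (median log2 -3.27, percentile 0). The 9 included the chemokine gene Ccl1 (1045 against 0.1115 UPM, 1 UMI; 9372-fold, 1682 to 370233), and the 3 were Il17a (55.6-fold, 44 to 71.3), Il22 (43.59 UPM against 0, at least 115-fold) and Xcl1 (22.4-fold). Outside the lists, the amino acid transporter gene Slc7a8 (193-fold, 113 to 363) and Dach2 (299-fold, 82.5 to 2480) were among the largest on the ST2 side.

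ILC3 genes were on the pool side: of 13, 7 were higher there, 0 in the IL-18R- ST2+ library and 6 neither (median log2 4.33, percentile 100). They included the IL-23 receptor gene Il23r (93.75 against 0.6336; 148-fold, 63.2 to 457) and Ccr6 (53.4 against 0.2534; 211-fold, 58 to 1745). T cell markers moved with them, and gamma delta T cells that make IL-17 use these same genes: of 9 gamma delta T cell genes 8 were higher in the pool and 1 neither (median log2 5.1, percentile 100), and of 9 T cell genes 7 were higher and 2 neither (median log2 3.31, percentile 100). Examples are Trdc (1160 against 16.09 UPM; 72.1-fold, 60.5 to 86.6), the scavenger receptor gene Cd163l1 (545.3 against 2.281; 239-fold, 151 to 404), Sox13, a gamma delta lineage factor (64.21 against 0.1267), and Cd3d (677.9 against 13.43; 50.5-fold, 41.6 to 61.8). Restricted to clusters named as an ILC class, Cd3e turned to the ST2 side. Those names need Cd3e below 100 UPM, so the loss of its pool excess was fixed by the naming rule. Of 10 ILC1 and NK genes 9 were higher in the pool and 1 neither (median log2 4.02, percentile 100), among them Klrk1 (149.9 against 6.716 UPM; 22.3-fold, 17 to 30) and Gzmb (22.96 against 0.2534).

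ILC progenitor genes also favoured the pool: of 17, 9, among them the gated Il18r1, were higher there, 2 in the IL-18R- ST2+ library and 6 neither (median log2 1.2, percentile 100), or 6, 2 and 8 of 16 under TMM (median log2 0.69). Tcf7, a factor of early ILC and T cells, stood at 204.2 against 19.01 UPM (10.7-fold, 9.09 to 12.8), Zbtb16, the PLZF gene, at 80.37 against 5.068 (15.9-fold, 11.5 to 22.4) and Cd7 at 123.8 against 1.521 (81.4-fold, 46.4 to 158). Of 20 transcription factors of ILC 7 were higher in the pool, 3 in the IL-18R- ST2+ library and 10 neither (median log2 0.36, percentile 77.19), or 4 and 4 under TMM (median log2 0.05). The 3 included Gata3. None of 8 GFI1B partner genes was called (median log2 0.09, percentile 9.74).

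Of 15 residency and trafficking genes 7 were higher in the pool, 4 in the IL-18R- ST2+ library and 4 neither (median log2 0.68, percentile 97.72): S1pr1, the exit receptor (5.84-fold, 4.89 to 7), and Itgae on the pool side, Ccr8 (13.2-fold, 9.81 to 18.2) on the ST2 side. Cytokine receptors split 6, 5 and 5 of 16 (median log2 0.07, percentile 10.46), with Il1r1 (134.4 against 1.774 UPM) and Il18r1 (42.2-fold, 35.3 to 50.9) in the pool and Il1rl1 in the IL-18R- ST2+ library. Of 15 immediate early and heat shock genes 2 (Hspa1a and Hspa1b) were higher in the pool, 2 (Fosb, and Nr4a1 at 2267 against 558.9 UPM) in the IL-18R- ST2+ library and 11 neither (median log2 0.08, percentile 60.58). The cytokine receptor, immediate early and GFI1B partner medians changed sign under TMM (-0.21, -0.20 and -0.20). Of 5 interferon response genes 3 were higher in the pool and 2 neither (median log2 1.29, percentile 99.18), with Ifi27l2a at 158 against 20.91 UPM.

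B cell, myeloid and stromal markers followed the pool here too, and so did cycling genes: B cell 4 of 5 higher (median log2 2.17, percentile 98.88), myeloid 4 of 5 (2.43, percentile 99.98), stroma, endothelium and epithelium 5 of 7 with 1 higher on the ST2 side (2.09, percentile 99.94), and cycling 6 of 9 (2.12, percentile 99.99). The stromal median turned below 0 without the myeloid, B cell, erythroid and stromal clusters. All 3 platelet and erythroid genes, which are globin genes, were higher in the IL-18R- ST2+ library (median log2 -7.71, percentile 0.01), with 99.2% of its Hbb-bs UMIs in 3 cells, and their direction turned when all barcodes were kept. No mast cell and basophil gene reached the minimum level.

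The library labelled IL-18R- CD103- GFP- had most ILC1 and NK and T cell genes on its side against the IL-18R- ST2+ library, and most ILC2 genes on the other. Since the pool was compared with the same ST2 library, likeness between these comparisons is partly built in. T-bet directs interferon gamma production, and CXCR3 brings such cells to inflamed tissue. Of 5736 measured genes 549 were higher in the library labelled IL-18R- CD103- GFP- and 310 in the IL-18R- ST2+ library (63.9%), or 447 and 389 (53.5%) under TMM and 431 and 408 (51.4%) under median of ratios.

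Of 16 ILC2 genes 13, again with Il1rl1, were higher in the IL-18R- ST2+ library, 0 in the other and 3 neither (median log2 -4.39, percentile 0), with Il5 at 168.5 against 0.4167 UPM (404-fold, 158 to 1486), Il13 at 178.8 against 0.8334 (215-fold, 109 to 498) and Hs3st1, which shapes heparan sulfate, at 351.2 against 4.688 (74.9-fold, 55.8 to 103). Of 15 secreted mediators 9 were higher in the IL-18R- ST2+ library, 5 in the library labelled IL-18R- CD103- GFP- and 1 neither (median log2 -3.66, percentile 0). Of 10 ILC1 and NK genes 9 were higher in the library labelled IL-18R- CD103- GFP- and 1 neither (median log2 4.92, percentile 100), including Tbx21 (24.59 against 0.2534 UPM; 97-fold, 26.6 to 806), Klrd1 (55.4-fold, 36.8 to 87.7) and Nkg7, a cytotoxic granule gene (36.2-fold, 27.5 to 48.6). Cxcr3 stood at 117 against 0.2534 UPM (462-fold, 128 to 3817). T cell markers moved with these genes: of 11 T cell genes 9 were higher and 2 neither (median log2 3.99, percentile 100), and of 9 gamma delta T cell genes 8 and 1 (median log2 5.29, percentile 100), with Trdc at 1709 against 16.09 UPM (106-fold, 89.2 to 128) and Cd3d at 811.9 against 13.43 (60.5-fold, 49.9 to 73.9).

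Of 11 ILC3 genes 6 were higher in the library labelled IL-18R- CD103- GFP- and 5 neither (median log2 4.09, percentile 100), or 6 and 1 of 12 under TMM (median log2 2.23), with Il22 at 69.28 UPM against 0 (at least 182-fold, 51.4% of UMIs in 3 cells). Of 15 ILC progenitor genes 7 were higher in the library labelled IL-18R- CD103- GFP-, 2 in the IL-18R- ST2+ library and 6 neither (median log2 0.88, percentile 100), with Tcf7 9.61-fold higher in the former and Kit 11.3-fold higher (9.74 to 13.1) in the latter. Of 21 transcription factors of ILC 8, 3 and 10 fell in these groups (median log2 0.26, percentile 78.16), or 8 and 5 under TMM, with Tbx21 and Zbtb16 among the 8. None of 8 GFI1B partner genes was called (median log2 -0.03, percentile 7.34).

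Of 13 residency and trafficking genes 6 were higher in the library labelled IL-18R- CD103- GFP-, 4 in the IL-18R- ST2+ library and 3 neither (median log2 0.51, percentile 99.03), with Ccr7 at 84.28 against 6.462 UPM in the former and Ccr8 at 69.31 against 1.979 in the latter. Cytokine receptors split 6, 4 and 6 of 16 (median log2 0.41, percentile 98.66). Of 15 immediate early and heat shock genes 2 were higher in the library labelled IL-18R- CD103- GFP-, 4 in the IL-18R- ST2+ library and 9 neither (median log2 -0.25, percentile 2.07; 0.21 with clusters named as an ILC class only), and of 5 interferon response genes 3 were higher in the former and 2 neither (1.03, percentile 99.55). Few B cell, myeloid, stromal and cycling genes were measured here: B cell 1 of 2 higher (median log2 1.13, percentile 66.79), myeloid 2 of 4 (0.62, percentile 93.22; 1 and 1 under TMM), stroma, endothelium and epithelium 1 of 4 with 2 on the ST2 side (-0.28, percentile 9.59), and cycling 0 of 3 (0.33, percentile 71.88). The myeloid gene S100a9 had 87.4% of its UMIs in 3 cells. All 3 platelet and erythroid genes were higher in the IL-18R- ST2+ library (median log2 -9.68, percentile 0.01). They are globin genes, and 1 cell held 11990 of the 12649 globin UMIs of that library. No mast cell and basophil gene reached the minimum level.

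Within single classes the pool and the library labelled IL-18R- CD103- GFP- can be compared apart from the shares of the classes, but not from mixture inside a class. Cells of 1 library are not replicates, so these are again values of 2 libraries. In gamma delta T cell-like cells (772 and 1114), 7 of 5622 measured genes were higher in the pool and 26 in the library labelled IL-18R- CD103- GFP-, against 0 and 0 under counting error alone. Itgae (120.3 against 4.612 UPM; 26.1-fold, 17.1 to 41.6) and Ccr6 (54.52 against 8.021; 6.8-fold, 4.82 to 9.8) led the pool. Cxcr3 (152.6 against 61.09; 2.5-fold, 2.15 to 2.91), Klrk1 (177.5 against 87.39) and Cxcl10 (2.82-fold) were on the other side, with 5 of 7 ILC1 and NK genes (median log2 -1.03, percentile 0). At resolution 2.0 a gamma delta T cell-like cluster with Cxcr3 and Klrk1 among its leading genes held 102 and 301 cells, so composition inside the class is not removed. Il18r1 was alike, 809.5 and 768.4 UPM. Of the ILC3 genes 1 of 12 was higher in the pool (median log2 0.28, percentile 100), and all 9 gamma delta T cell genes were neither (-0.02).

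In ILC1 and NK-like cells (162 and 90), 381 and 309 of 6139 genes were called, against 106 and 88 under counting error alone, so single calls here are weak. Of 17 ILC progenitor genes 6 were higher in the pool, 1 in the library labelled IL-18R- CD103- GFP- and 10 neither (median log2 0.74, percentile 100). The class is a different mixture in each library: at resolution 2.0, 116 of its pool cells and 24 of its cells from the library labelled IL-18R- CD103- GFP- fell in the progenitor-like cluster, 44 and 65 in the ILC1 and NK-like cluster and 2 and 1 in others, so composition is not removed here either. Gzma (305.3 UPM against 0, at least 49.4-fold, in 4.94% of pool cells) and the Notch target gene Hey1 (86.66 against 4.119; 21-fold, 5.69 to 176) were higher in the pool, Ifng (67.97 against 11.13; 6.11-fold, 3.18 to 12.4) in the library labelled IL-18R- CD103- GFP-. Hmgn3, also higher in the pool, turned direction with resolution 0.5 clusters. In the unnamed cluster 5 (392 and 154 cells) 100 and 106 of 5752 genes were called, against 30 and 23.5 under counting error alone. At resolution 2.0, 63 and 47 of its cells were T cell-like, 9 and 7 gamma delta T cell-like, and 320 and 100 unnamed. Composition is thus not removed in cluster 5. Itgae stood at 126.1 against 1.258 UPM (1 UMI) and Lgals3 4.43-fold higher in the pool, and Arg1 (56.63 against 0.9592; 59-fold, 15.4 to 502) and Cxcr3 (7.06-fold) in the library labelled IL-18R- CD103- GFP-.

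Shares of cells with a UMI are given after thinning each cell to 2000 UMIs. They depend on level as well as on how many cells use a gene. Gata3 had a UMI in 17.42% of pool cells, 14.73% of the library labelled IL-18R- CD103- GFP- and 73.95% of the IL-18R- ST2+ library, and Rora, shared by ILC2 and type 17 cells, in 67.11%, 63.46% and 85.66%. Tcf7 was seen in 27.26%, 24.77% and 2.88%, and Tbx21 in 2.08%, 4.32% and 0.13%. Il17a marked 28.06%, 21.59% and 0.31%, Ifng 1.34%, 4.59% and 0.06%, and Il5 0.24%, 0.11% and 11.9%. Il18r1 was present in 68.83%, 63.25% and 2.82%. In B cell-like and myeloid-like cells of the pool (median depth 3516 UMIs, against 4930 for all pool cells), Gata3, Rora, Tcf7, Tbx21, Itgae, Il17a, Ifng and Il5 were seen in 0% of 66 cells (upper limit 5.44%) and Il18r1 in 3.03% (0.37 to 10.52). The Tbx21, Ifng and Il5 shares of the pool lie under that limit. In the library labelled IL-18R- CD103- GFP- all were 0% of 13 such cells (upper limit 24.71%; median depth 4041 against 4768 UMIs) and in the IL-18R- ST2+ library 0% of 11 (28.49%; 3077 against 4568). Only Rora, Il18r1 and, barely, Tcf7 in the former and Gata3 and Rora in the latter exceed these limits.

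**Figure D3:**
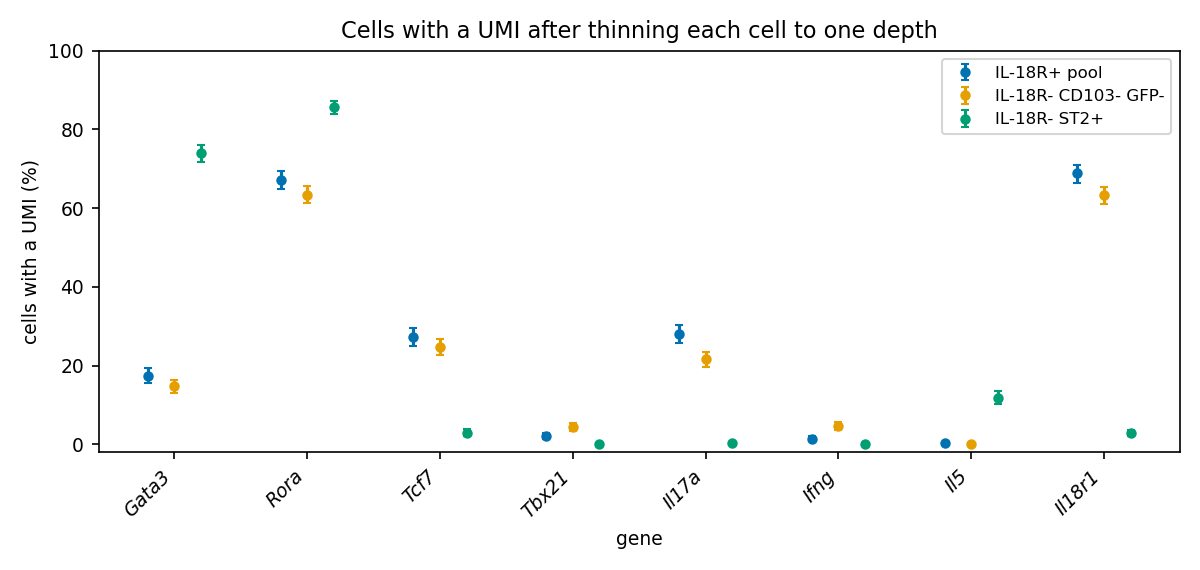
Percent of cells with at least 1 UMI after thinning to 2000 UMIs per cell, by gene and library. Gata3 marks 73.95% of the IL-18R- ST2+ library, and Il17a marks 28.06% of the pool and 21.59% of the library labelled IL-18R- CD103- GFP-.

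Since the pool mixes a CD103+ GFP- sort with a CD103- GFP+ sort, Itgae is the only sort transcript that could separate them. An Itgae UMI was found in 33.78% of pool cells, or 18.77% after thinning. Cells with Itgae were spread over clusters, counted without thinning: 53.15% of cluster 9 (229.2 UPM, 190.4 to 273.7), 47.37% of cluster 11 (19 cells), 46.88% of the deeply sampled cycling cluster 13, 43.88% of cluster 5, 39.47% of cluster 3 and 35.52% of cluster 1, but 6.79% of the ILC1 and NK-like cluster 7 (14.31 UPM). B cell-like and myeloid-like cells had 0%. Clusters 5 and 1 held 29.4% and 28.4% of all Itgae UMIs of the pool.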

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

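All tests of explanations in this section were chosen only after the result was seen. Barcodes that the cell filter left out held many globin UMIs, transcripts of red blood cells, and they stand out because the main comparisons leave these barcodes out. The sums were 122245 in the pool, 7888 in the library labelled IL-18R- CD103- GFP- and 50934 in the IL-18R- ST2+ library. They are 87.61%, 31.68% and 30.61% of the 139538, 24896 and 166400 UMIs in the removed barcodes, and 14, 1 and 6 of these barcodes were more than 50% globin. Kept cells held 59, 10 and 12649 globin UMIs. With all barcodes kept, Hba-a1 against the IL-18R- ST2+ library read 0.73 log2 in the pool, where the filtered cells gave -7.71. No explanation by the design was tested, since none of the groups is defined by red blood cells.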

How the results depend on the processing

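Most alternatives were fixed before the data were examined, and those named as added were chosen after. No paired analysis was possible because the labels give no replicate numbers shared between libraries. Directions are pool over the library labelled IL-18R- CD103- GFP- (first pair), pool over IL-18R- ST2+ (second pair) and the label library over IL-18R- ST2+ (last pair), in log2. Of 2928 alternative values for single genes, 20 changed direction, 596 moved and 2312 stayed the same. Of 265 for gene lists, 10 changed direction in lists whose median stood outside the middle 95% of random lists, 74 moved and 181 stayed. Medians nearer to those of random lists also changed sign, and are not among the 10. Of 126 values for genes within a class 1 changed direction, 5 moved and 120 stayed, and of 324 class shares 80 moved and 244 stayed. Shares of cells with a UMI moved in 67 of 90 values, since deeper cells show more genes. Counts of genes by size moved in 13 of 76 values, and within classes all 18 stayed.

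Only clusters named as an ILC class turned more results than any other setting. It drops the gamma delta T cell-like, T cell-like, unnamed, cycling, myeloid, B cell and stromal clusters. Which of these removals turned each result was not tested. The sums left were 1295536 UMIs in the pool and 797761 in the library labelled IL-18R- CD103- GFP-. In the first pair the counts by size became 321 and 297, and Mt1 read -1.28, Ccl5 1.17, Ly6c2 2.47, Gramd3 0.39, Klrd1 0.075, Ccr6 -2.825 and Lef1 1.46. The ILC1 and NK list read 0.075, ILC3 -0.88, B cell -0.26, myeloid -0.003 and immediate early and heat shock -0.64. In the second pair Cd3e, which the ILC names themselves limit, read -0.92, Hspa1b -2.32 and Thy1 -0.60. In the last pair the immediate early and heat shock list read 0.21.

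Without myeloid, B cell, erythroid and stromal clusters, which was added, 59 genes were higher in the pool in the first pair where the main count is 148. Ebf1 read -0.56, Cd14 -0.082, the B cell list -0.065 and the stromal list -0.001, because the cells that carry these genes are left out, and in the second pair the stromal list read -0.12. Without cycling clusters Birc5 read -0.065 and Rrm2 -0.012 in the first pair for the same reason. Under the stricter filter S100a9 read -0.20, and the cause was not tested. With all barcodes the second pair gave Hbb-bt 0.655, Hba-a2 0.72, Hba-a1 0.73, Hbb-bs 0.84 and the platelet and erythroid list 0.73, because globin-rich barcodes come back in.

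Without a minimum level the counts by size were 1997 and 380, 3148 and 986, and 1865 and 1494 in the 3 pairs, as genes with few UMIs enter. TMM gave 476 and 388 in the second pair and median of ratios 450 and 412. TMM gave an Il18r1 ratio of 1.02 in the first pair, outside the counting interval of 1.08 to 1.16, and 34.7 in the second (main value 42.2). Why the library totals and these factors differ was not tested.

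Class shares, in percent, depended on the clustering and on the naming rule. The first naming rule was applied to the main clusters, so its shares differ by naming alone. For the other settings the cause was not tested. Each library on its own gave gamma delta T cell-like shares of 39.46, 14.8 and 0, ILC2-like 0, 0 and 24.02, ILC1 and NK-like 2.05, 0 and 0, and ILC3-like 0 in the pool and in the library labelled IL-18R- CD103- GFP-. Both the clusters and the cells that markers are compared with change in that setting. ILC2-like shares in that library were 0.43 with 15 principal components, 0.37 without cycling and immediate early genes, 1.58 with all barcodes and 0.32 with the first naming rule. In the IL-18R- ST2+ library they were 94.91, 95.59, 95.56 with Scrublet calls kept, and 47.18 with the first rule, and in the pool 0.89 with all barcodes. ILC1 and NK-like shares of the pool were 2.66 at resolution 2.0, 6.53 with 15 components, 6.34 without cycling and immediate early genes and 11.84 with the first rule. In the library labelled IL-18R- CD103- GFP- they were 7.26 at resolution 0.5, 3.47 at 2.0 and 24.68 with the first rule. In the IL-18R- ST2+ library they were 0 at resolution 2.0, with 15 components, without cycling and immediate early genes and with all barcodes, and 0.99 with the first rule, which was added. ILC3-like shares were 0 in the pool and in the library labelled IL-18R- CD103- GFP- at resolution 0.5, with 15 components and without cycling and immediate early genes, and 0 in the pool with all barcodes. Within ILC1 and NK-like cells Hmgn3 read -0.17 with resolution 0.5 clusters, and the cause was not tested. Thinned to 2000 UMIs, 18.77% of pool cells had an Itgae UMI, because thinning removes UMIs.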

Other observations

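All tests in this part were chosen only after the results were seen, and the designs of the sorts gave no further library to test them in. ILC2-like cells of the IL-18R- ST2+ library fell into 3 clusters with different use of effector genes. Cluster 4, with 38.98% of that library, held Il5 at 309.3 UPM (290.8 to 328.7), against 64.13 (56.16 to 72.91) in cluster 2 and 70.99 (50.24 to 97.45) in cluster 8. Areg, the amphiregulin gene, stood at 2553 UPM in cluster 4, 1060 in cluster 2 and 515.6 in cluster 8, and Calca, which encodes the neuropeptide CGRP, at 814.1, 374 and 80.34. Il5 and Areg helped to form these clusters, so the gap is partly built in.

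Il18r1 transcript in the library labelled IL-18R- CD103- GFP- has several possible explanations. Free RNA was excluded: after thinning, 10.71% (2.27 to 28.23) of its 28 B cell-like, myeloid-like and stroma-like cells had an Il18r1 UMI, against 73.45% (70.74 to 76.04) of 1100 gamma delta T cell-like cells. A swap with the pool was excluded by Itgae, 3.44 against 99.8 UPM, and a swap with the IL-18R- ST2+ library by Il1rl1, 5.52 against 868 UPM. A surface gate that differs from the transcript stays open, with Il18r1 in the pool at 1.12 times its level there, because no protein was measured. A wrong label on a library from outside these 3 cannot be told apart from it.

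T cell transcripts in a sort meant to be lineage negative could come from several sources. Free RNA is argued against by Cd3e in clusters whose names do not use it. Cd3e was 0 in the myeloid-like and B cell-like clusters and 80 UPM in the stroma-like cluster. Gamma delta T cell-like clusters held 822.6 to 1004.6 UPM. Why the stroma-like cluster held some was not tested. ILC1 and NK-like cells of the same libraries held Cd3g at 24.1 UPM against 2093 in gamma delta T cell-like cells. Both names rest on Cd3e, so that gap is partly built in. Germline receptor transcripts, which ILC can make, stay open for the receptor genes, because counts per gene do not show rearranged receptors. They would not account for the CD3 chain genes, which do not rearrange. Cd3g was 120 UPM and Cd3d 2.89 (1.81 to 4.38) in ILC2-like cells, against 2093 and 1034 in gamma delta T cell-like cells. The class names rest on Cd3e, so that gap too is partly built in. The T cell-like cluster led by Foxp3 held Cd3e at 601.9 UPM, below the gamma delta T cell-like clusters. Doublets of a T cell and an ILC would hold more UMIs, but the median of gamma delta T cell-like cells was 0.881 times that of ILC1 and NK-like cells in the library where it was higher. In the pool ILC1 and NK-like cells were deep (median 7253 against 4930 UMIs for all cells), so the comparison says little there. Expected doublet rates were 1.35% and 1.522% in the 2 libraries, while this class held 46.65% and 59.51% of their cells. Doublets at those rates would be a small part of it. For the CD3 genes these levels argue against germline receptor transcripts as the only source. For the receptor genes, T cells inside the gate cannot be told apart from germline transcripts in ILC by these counts. Whether the gate should have excluded such cells is unknown, because the lineage antibodies are not given in the sources used here.

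The absence of Gfi1b from all libraries may have 2 explanations, and they cannot be told apart. Depth allows a level of up to 0.334 UPM in the pool, well below most factors named here. A reporter allele whose transcripts end outside the counted gene could also give 0 UMIs, and transcript ends are not in the counts. No biological explanation was tested, as the GFP+ sort is mixed with another sort in 1 library.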
